A study of Rattus norvegicus with 172 samples.

How the data were processed

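Liver RNA was measured by mRNA sequencing in 70 male Fischer rats that received furan, 3-methylfuran or no compound for 90 days. Furan is a heterocyclic food contaminant, and 3-methylfuran carries a methyl group on its ring. Per the labels, total RNA was taken from flash-frozen liver with miRNeasy kits. The 3-methylfuran libraries were made with the TruSeq Stranded mRNA protocol and the furan libraries with the later Stranded mRNA prep kit, so library kit and compound changed together. The submitters' processing notes name STAR 2.7.1a, featureCounts 2.0.0, DESeq2 1.26.0 and the Rnor 6.0 genome build. The annotation release, the strand setting and the handling of multimapping reads were not given in the sources used here.

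The deposited count tables hold an integer read count per gene and sequencing run, which the authors made with featureCounts and left without normalization. The deposited furan comparison table gives a signed fold change per dose, a unit other than a plain ratio, in which the authors wrote a decrease as a negative reciprocal; 0 of its values lay between -1 and 1. The deposited 3-methylfuran comparison table gives a plain ratio or fold per dose. In both comparison tables the authors give an adjusted p-value per gene and dose. How the runs of a rat were combined for these tables, and whether fold changes were shrunken, was not given in the sources used here. The array data that the series design mentions were not analysed here.

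Each library was sequenced in 2 runs (furan, 38 rats, 76 columns) or 3 runs (3-methylfuran, 32 rats, 96 columns), 172 runs in all. Counts of the runs of a rat were summed, since runs are technical. Over genes with at least 20 counts, the chi-square per degree of freedom between runs of a rat was 1.01 to 1.07 for furan and 1.0 to 1.04 for 3-methylfuran. Between 2 rats of the same group it was at least 6.15 and 6.82. Doses came from the labels. The labels describe all control rats alike, and controls were assigned to an experiment by the number in the sample title, which matches the columns of each count table. Every count column was matched to a sample.

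Genes were identified by Ensembl ID, and symbols came from the deposited comparison tables. Of the 32883 genes in each count table, 19777 had a symbol there, and the 13106 without one held at most 4 counts in total. No coordinates are printed, since the deposited tables hold none and the available annotation is of a later build (GRCr8) than the one the reads were mapped to.

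Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr on the dose groups (minimum count 10), libraries were scaled by TMM, and each dose was tested against the controls of its own experiment with the edgeR quasi-likelihood F test (robust). One fit per experiment held all its dose groups. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is the estimate divided by the square root of F. CPM values are counts scaled by library size and TMM factor, given as mean and SD over rats. Dose trends used dose in mg/kg bw/day as a linear term. The difference between the compounds was tested in a fit of all 70 rats with 1 coefficient per group, as the effect of a furan dose over its controls minus the effect of a 3-methylfuran dose over its own controls. Its 95% interval uses the t distribution with 61 degrees of freedom. Doses of the compounds do not match, so 3-methylfuran 1.0 was set against furan 2.0 and furan 0.5.

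Before the data were examined, 22 gene lists and 10 lists of cell type markers were fixed. The gene lists were NRF2 and electrophile response, glutathione S-transferases, cell cycle, p53 targets, ATF4 and unfolded protein response, heat shock, bile acids, cholesterol synthesis, fatty acid synthesis, PPAR alpha targets, xenobiotic P450 genes, CAR and PXR targets, AHR targets, glucose metabolism, iron handling, acute phase, interferon response, extracellular matrix, oncofetal markers, circadian clock, and pericentral and periportal hepatocyte genes. The marker lists covered cholangiocytes, stellate cells, macrophages, T and NK cells, B and plasma cells, neutrophils, sinusoidal endothelium, red blood cells, pancreatic acinar cells and adipocytes. Of their 535 different symbols, 62 had no match in the deposited tables, among them Nqo1, Hmox1, Mcm5, Cdh1 and Tat. Lists were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01), again with an estimated correlation, and with fry; Benjamini-Hochberg was applied over the lists of a comparison. Called members are counted over all genes and also adjusted over the list alone.

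The rule for named genes was fixed at the same time. Cyp2e1, the P450 that activates furan, is followed in every comparison. At the highest doses the 8 called genes with the largest change in each direction are named, given a proper symbol, a mean of at least 1 CPM in the higher group and every treated rat on the same side of the control mean. From each list up to 4 called and 2 uncalled members were taken. At lower doses the rule takes 5 genes per direction by size, and for differences and trends the 5 with the smallest adjusted p per direction. Where names would repeat, some were left out, and a gene named in one comparison may be followed elsewhere.

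The tests were tried on simulated negative binomial counts, drawn from control means and fitted dispersions, with changes of known size in 200 genes. Simulated genes varied independently between rats, and far more genes were called in the real data at the highest doses, so the shares may not carry over. For furan 2.0 the fit recovered 32.7% of 1.25-fold, 67.3% of 1.5-fold, 88% of 2-fold and 100% of 4-fold changes, and 2.1% of its calls were false. For 3-methylfuran 1.0 it recovered 51%, 84%, 92% and 100%, with 5.8% false. For the difference between these doses the shares were 20%, 60%, 72% and 96%, with 6.1% false. For furan 0.5 minus 3-methylfuran 1.0 they were 18%, 54%, 80% and 96%, with 9.5% false, and the differences of the lower doses recovered 10% of 1.25-fold changes. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter on low counts, a mean of at least 1 CPM, a fold threshold of 1.5, run 1 alone, each dose fitted with its controls alone, dose rank in place of dose, trends without the highest dose, and the highest doses without each rat in turn. Shared controls were handled by simulation and by splitting the controls. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the tables and figures.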

Results

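Poly(A) RNA of liver was sequenced from 70 male rats in 9 groups. The furan experiment held 8 control rats and 8, 8, 7 and 7 rats at 0.03, 0.12, 0.5 and 2.0 mg/kg body weight per day. The 3-methylfuran experiment held 8 controls and 8 rats each at 0.02, 0.075 and 1.0 mg/kg body weight per day. Total counts per rat ran from 11.4 to 27.7 M for furan (median 16.3) and from 11.1 to 50 M for 3-methylfuran (median 14.9). The 3-methylfuran 0.075 group was the deepest (13.2 to 50 M, median 24.2), beside 11.1 to 18.9 M in its controls. Between 15636 and 17706 genes were detected per furan rat and between 15267 and 17541 per 3-methylfuran rat. The 10 most abundant genes took 25.3 ± 1.3% of counts in furan rats (SD, n = 38) and 28.1 ± 0.9% in 3-methylfuran rats (n = 32). At furan 2.0 that share was 23 ± 1.3% (n = 7), beside 26 ± 0.5% in the controls. TMM factors were 1.021 to 1.405 at furan 2.0 and 0.894 to 0.963 in its controls. They were 1.046 to 1.226 at 3-methylfuran 1.0 and 0.919 to 0.974 in its controls. Rises and falls at these doses are relative to that scaling, which assumes that most genes do not change.

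The highest furan dose was compared with its controls to learn which liver genes the parent compound moved. Genes of electrophile handling stood far above control. Gstp1 (ENSRNOG00000018237), the placental-form glutathione S-transferase used as a marker of altered rat hepatocytes, rose from 13.0 ± 3.55 to 144 ± 60.4 CPM (mean ± SD, n = 8 and 7; log2 fold change 3.46 ± 0.29 SE). Aldh1a7 (ENSRNOG00000017878), an aldehyde dehydrogenase, rose by 5.04 ± 0.34, and Gpx2 (ENSRNOG00000055672), a selenium-dependent glutathione peroxidase, by 4.75 ± 0.53. Phgdh (ENSRNOG00000019328), the first enzyme of serine synthesis, rose from 1.96 ± 2.69 to 36.6 ± 4.88 CPM (4.23 ± 0.67), while Sds, which breaks serine down, fell by 3.67 ± 0.74. Scd, the stearoyl-CoA desaturase, fell by 2.77 ± 1.04, and Fasn, the fatty acid synthase, went from 332 ± 183 to 96.8 ± 12.5 CPM. All these genes lay on the same side of the control mean in 7 of 7 rats, which the naming rule required of genes named by size. Their edgeR adjusted p ran from 8.94e-14 (Aldh1a7) to 0.0286 (Scd). Other large increases were those of Fam25a (7.14 ± 1.16), the macrophage receptor gene Trem2 (4.85 ± 1.02), the AP-1 subunit gene Fosl1 (4.42 ± 0.84) and the matrilin gene Matn4 (4.35 ± 0.5). A1bg, a plasma glycoprotein gene, fell by 6.21 ± 1.38 and Cpa1, a carboxypeptidase gene, by 4.82 ± 1.07; both varied widely among the controls, A1bg from 0.405 to 60.6 CPM. Cyp2e1 (ENSRNOG00000012458) stood at 3015 ± 959 CPM beside 3176 ± 621 in controls (-0.08 ± 0.16, adjusted p = 0.731).

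Cell cycle genes rose together at furan 2.0. Of 30 members tested, 29 rose and 0 fell, with a median log2 fold change of 1.38; the proliferation antigen gene Mki67 rose by 1.88 ± 0.33 (from 4.71 ± 2.08 to 17.2 ± 6.94 CPM), the replication helicase gene Mcm3 by 1.62 ± 0.28 and the thymidylate synthase gene Tyms by 1.09 ± 0.15. Camera called the list (adjusted p = 3.58e-11; adjusted p = 0.505 with an estimated correlation). In the NRF2 and electrophile list 16 of 23 members rose and 0 fell, among them the bile conjugate exporter gene Abcc3 (2.4 ± 0.2) and Gsta3 (3.34 ± 0.47); camera gave an adjusted p of 6.34e-07 (adjusted p = 0.403 with an estimated correlation). Oncofetal markers rose in 7 of 8 members, including Cd24 (2.83 ± 0.22) and the aldo-keto reductase gene Akr1b8 (3.91 ± 0.52), with a camera adjusted p of 0.000259 (adjusted p = 0.403 with an estimated correlation). Heat shock genes rose in 5 of 12 members (6 adjusted over the list alone; camera adjusted p = 0.0247; adjusted p = 0.518 with an estimated correlation).

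Genes of hepatocyte metabolism fell at the same dose. Among xenobiotic P450 genes 14 of 23 fell and 4 rose (camera adjusted p = 0.000727; adjusted p = 0.505 with an estimated correlation); Cyp2d1 fell by 0.97 ± 0.1 and Cyp1a2 by 0.98 ± 0.15, while Cyp3a62 rose by 1.86 ± 0.2. Of 22 bile acid genes 15 fell (16 adjusted over the list alone) and 3 rose, with the bile acid ligase gene Slc27a5 going from 890 ± 122 to 452 ± 118 CPM (camera adjusted p = 0.000727; adjusted p = 0.442 with an estimated correlation). Fatty acid synthesis genes fell in 11 of 13 members, with 1 higher adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.518 with an estimated correlation). PPAR alpha targets fell in 14 of 26 with 1 higher (camera adjusted p = 0.000259; adjusted p = 0.518 with an estimated correlation), and cholesterol synthesis genes in 10 of 24 (0.00744; adjusted p = 0.598 with an estimated correlation). Periportal genes fell in 9 of 11 (camera adjusted p = 0.00135; adjusted p = 0.505 with an estimated correlation) and pericentral genes in 6 of 11, 7 adjusted over the list alone (0.0496; adjusted p = 0.518 with an estimated correlation). Acute phase genes fell in 8 of 14 with 1 higher, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00835; adjusted p = 0.505 with an estimated correlation). All 5 red blood cell markers fell, such as Slc4a1 by 1.05 ± 0.16 (camera adjusted p = 0.00374; adjusted p = 0.505 with an estimated correlation).

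Matrix and bile duct genes rose at furan 2.0, unevenly between rats. Extracellular matrix genes rose in 22 of 31 members (25 adjusted over the list alone) and fell in 1; the camera adjusted p was 0.00119 (adjusted p = 0.598 with an estimated correlation). Cholangiocyte markers rose in 13 of 16 (14 adjusted over the list alone) and fell in 2, with a camera adjusted p of 0.000259 (adjusted p = 0.505 with an estimated correlation). The type I collagen gene Col1a1 (ENSRNOG00000003897) rose by 3.09 ± 0.64, the periostin gene Postn by 6.37 ± 1.14, the chloride channel gene Cftr by 4.1 ± 0.52 and Spp1, osteopontin, by 5.15 ± 0.94. Col1a1 lay between 86.1 and 186 CPM in rats ME081_L, ME082_L, ME083_L and ME085_L and between 9.01 and 13.7 CPM in rats ME086_L, ME089_L and ME092_L, beside 10 ± 4.52 in controls. Gstp1 was 20.9 CPM in rat ME086_L and at least 118 CPM in the other 6 rats. Sinusoidal endothelial markers had a median log2 fold change of -0.33, with 0 of 14 higher and 3 lower (0 adjusted over the list alone).

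Camera called 15 of the 31 lists tested at furan 2.0, 6 higher and 9 lower, and fry called 22, these 15 among them in the same direction. With an estimated correlation 0 lists were called, 3 at an unadjusted p under 0.05. Among the lists that camera did not call, members rose and fell as follows: p53 targets 7 and 3 of 21, ATF4 genes 6 and 7 of 19, glutathione S-transferases 3 and 5 of 18, CAR and PXR targets 4 and 1 of 11, glucose metabolism 6 and 7 of 15, iron handling 3 and 4 of 10, interferon response 2 and 6 of 18, and clock genes 4 and 7 of 17. The p53 targets Ccng1 and Mdm2 rose by 0.94 ± 0.12 and 0.83 ± 0.12, and Hamp, the hepcidin gene of the iron list, fell by 1.39 ± 0.21. Of 3 AHR targets Cyp1a1 rose and Cyp1a2 fell. Stellate cell markers rose in 3 and fell in 3 of 12, macrophage markers rose in 3 of 15, and T and NK, B and plasma cell and neutrophil markers rose in 1 each of 9, 4 and 3. Both pancreatic acinar markers tested fell, and too few adipocyte markers were expressed for a test. Median and mean log2 fold change differed in sign for glutathione S-transferases (-0.19 and 0.19), ATF4 genes (-0.08 and 0.4), AHR targets (-0.24 and 0.14) and clock genes (-0.24 and 0.06), and stellate cell markers had a median of 0.05 with a camera direction of lower. In all, edgeR called 5923 of 12727 genes, 3054 higher and 2869 lower, and 2229 of them changed at least 1.5-fold. Leaving out each rat in turn gave 5353 to 6355 calls.

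**Figure D1:**
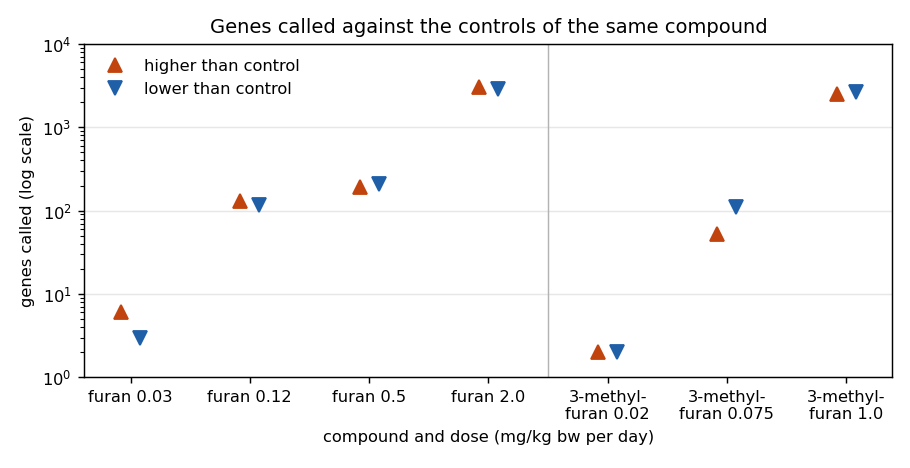
Number of genes called by edgeR at each dose against the concurrent controls (log axis), higher and lower genes as upward and downward triangles, for furan and 3-methylfuran. Calls numbered 5923 for furan and 5207 for 3-methylfuran at the highest doses, and 9 and 4 at the lowest.

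The highest 3-methylfuran dose was compared with its own controls in the same way. Phgdh rose from 1.05 ± 0.764 to 31.4 ± 12.3 CPM (n = 8 and 8, log2 fold change 4.93 ± 0.43). Gstp1 rose from 10.3 ± 6.11 to 131 ± 207 CPM (3.68 ± 0.59) and Aldh1a7 by 3.98 ± 0.6. Each lay above the control mean in 8 of 8 rats, a condition of the naming rule for genes named by size. The Gstp1 mean rests in part on rat ME587L, at 638 CPM, while the other 7 rats lay between 22.3 and 105 CPM. Prr32 (4.46 ± 0.31), Tsx (3.91 ± 0.54), Ildr1 (3.73 ± 0.39) and Erich5 (3.36 ± 0.26) were also among the largest increases. The methyltransferase gene Inmt fell by 3.23 ± 0.35, Gimd1 by 3.16 ± 0.33 and the NADPH oxidase gene Nox4 by 2.54 ± 0.31. Their adjusted p in edgeR ran from 3.22e-12 (Prr32) to 8.94e-06 (Gstp1). Cyp2e1 rose by 0.48 ± 0.13, from 2195 ± 375 to 3053 ± 311 CPM (adjusted p = 0.00393, above the control mean in 8 of 8 rats).

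Cell cycle genes rose in 27 of 30 members at 3-methylfuran 1.0 and fell in 0, with a median of 1.39; Mki67 rose by 1.83 ± 0.36, Mcm3 by 1.7 ± 0.2 and Tyms by 1.2 ± 0.11 (camera adjusted p = 4.74e-11; adjusted p = 0.377 with an estimated correlation). The NRF2 list rose in 13 of 22 and fell in 1, with Abcc3 at 2.69 ± 0.42 and the epoxide hydrolase gene Ephx1 at 1.09 ± 0.18 (camera adjusted p = 0.00075; adjusted p = 0.549 with an estimated correlation). Oncofetal markers rose in 4 of 5, Cd24 by 1.81 ± 0.19 (camera adjusted p = 0.00881; adjusted p = 0.281 with an estimated correlation). P450 genes fell in 15 of 22 and rose in 4 (camera adjusted p = 0.00075; adjusted p = 0.377 with an estimated correlation); Cyp2d1 fell by 1.05 ± 0.07 and Cyp1a2 by 1.29 ± 0.19. Bile acid genes fell in 14 of 22 (15 adjusted over the list alone) and rose in 4, with Slc27a5 falling by 1.12 ± 0.13 (camera adjusted p = 0.00901; adjusted p = 0.281 with an estimated correlation). PPAR alpha targets fell in 14 of 26 (18 adjusted over the list alone) and rose in 1 (camera adjusted p = 0.000691; adjusted p = 0.549 with an estimated correlation). Extracellular matrix genes rose in 2 and fell in 6 of 28, with Col1a1 at 5.4 ± 2.32 CPM beside 6.52 ± 1.16 in controls (-0.27 ± 0.22, adjusted p = 0.329), and cholangiocyte markers rose in 4 and fell in 1 of 9, Epcam by 1.69 ± 0.12. Clock genes rose in 4 (5 adjusted over the list alone) and fell in 8 of 17, Per3 rising by 2.35 ± 0.2 and Dbp by 1.57 ± 0.16. Red blood cell markers fell in 3 of 5 and fatty acid synthesis genes in 5 of 13, Fasn from 1297 ± 921 to 388 ± 91.3 CPM.

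Camera called 6 of 29 lists at 3-methylfuran 1.0, fry 18, and 0 were called with an estimated correlation, 3 at an unadjusted p under 0.05. Median and mean differed in sign for ATF4 genes (-0.4 and 0.11; 4 rose and 11 fell of 19), glutathione S-transferases (-0.04 and 0.28), CAR and PXR targets (-0.14 and 0.21), clock genes (-0.27 and 0.01) and cholangiocyte markers (-0.04 and 0.43). EdgeR called 5207 of 11930 genes, 2527 higher and 2680 lower, 1587 of them by at least 1.5-fold. Without each rat in turn the count was 4880 to 5196.

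**Figure D2:**
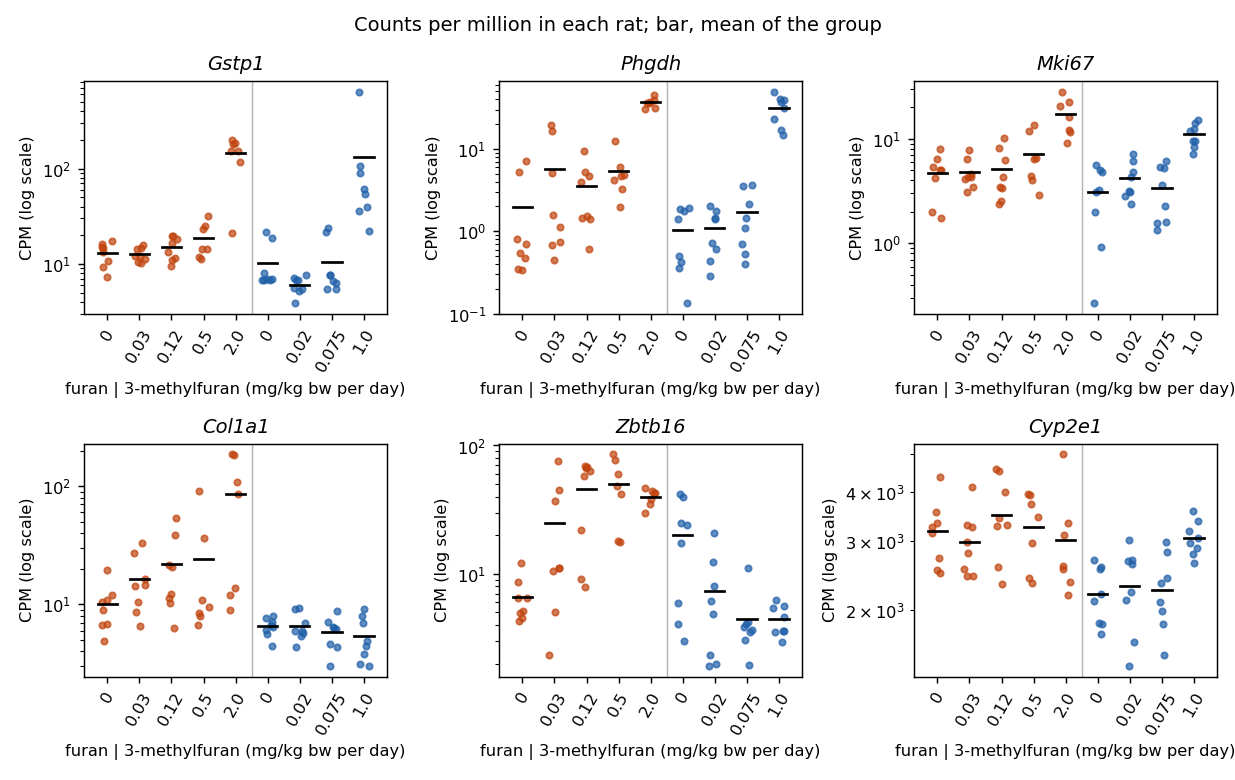
CPM of 6 genes in each rat (points, log axis) by dose group, with bars at the group mean. Gstp1, Phgdh and Mki67 were high at the highest dose of each compound, Col1a1 in 4 of 7 rats at furan 2.0, and Zbtb16 went opposite ways in the 2 experiments.

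Setting the compounds side by side asked how the methyl derivative differs from its parent. Their highest doses differ, 2.0 and 1.0 mg/kg body weight per day, so a difference of effects is a difference between these doses as well. Library kit and experiment, with its own controls, also went with the compound. Cell cycle genes and several metabolic genes were not called different: Mki67 differed by 0.04 ± 0.5 (95% interval -0.96 to 1.05), Mcm3 by -0.09 ± 0.35 (-0.78 to 0.61), Cyp2d1 by 0.08 ± 0.12 (-0.17 to 0.32) and Slc27a5 by 0.14 ± 0.18 (-0.21 to 0.49). For Gstp1 the difference of -0.23 ± 0.61 had an interval from -1.45 to 0.98 and for Phgdh, at -0.71 ± 0.88, from -2.48 to 1.06, so folds of either compound over the other stay possible. In the cell cycle list 1 of 30 members differed (median 0.05, camera adjusted p = 0.945), and in the P450 list 1 of 23 (median 0.07, camera adjusted p = 0.613). The P450 genes Cyp2c12 (-2.21 ± 0.51, interval -3.22 to -1.19) and Cyp2a3 (-0.45 ± 0.12, interval -0.7 to -0.2) were called lower with furan. The Cyp2c12 difference rests on furan controls that split into high and low rats, as given in the closing section. Matrix and bile duct genes differed: 13 of 31 matrix genes (19 adjusted over the list alone) and 9 of 16 cholangiocyte markers (11 adjusted over the list alone) had a higher effect at furan 2.0, 0 a lower one. Col1a1 differed by 3.35 ± 0.73 (interval 1.9 to 4.81), Cftr by 3.92 ± 0.75 and the elastin gene Eln by 1.73 ± 0.34, rising by 0.75 ± 0.26 with furan and falling by 0.99 ± 0.2 with 3-methylfuran. The Col1a1 difference rests on part of the furan 2.0 group, since rats ME086_L, ME089_L and ME092_L lay near control. Camera gave adjusted p of 2.86e-08 for matrix genes and 0.000403 for cholangiocyte markers (adjusted p = 0.667 with an estimated correlation for each; fry 0.0863 for each).

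Genes with the smallest adjusted p for this difference included Klf13 (1.92 ± 0.28), Zbtb16 (4.78 ± 0.75) and the microfibril-associated gene Adamtsl2 (2.57 ± 0.38), higher with furan, and Magi3 (-1.13 ± 0.16), Tent2 (-0.87 ± 0.13), Dennd4a (-0.77 ± 0.11) and Mest (-1.58 ± 0.25), higher with 3-methylfuran. Between furan 0.03 and 3-methylfuran 0.02 the intervals were 0.95 to 2.06 for Klf13, 1.91 to 4.85 for Zbtb16 and -0.63 to -0.13 for Tent2. Those of Adamtsl2, Magi3, Dennd4a and Mest spanned both signs there. A gap already present at the lowest doses may come from the controls or the experiments, which was not tested. Zbtb16, a transcription factor gene that glucocorticoids raise, rose by 2.6 ± 0.54 with furan and fell by 2.18 ± 0.5 with 3-methylfuran. That fall rests on 5 control rats at 17.5 to 42 CPM; the other 3 controls, at 2.98 to 5.91 CPM, lay with the dosed rats (2.92 to 6.28 CPM). Cyp2e1 differed by -0.56 ± 0.22 (interval -0.99 to -0.13, adjusted p = 0.0988 over all genes). Oncofetal markers differed in 3 of 8 members (5 adjusted over the list alone), Cd24 by 1.0 ± 0.31 and Akr1b8 by 2.76 ± 0.72 (camera adjusted p = 0.00426; adjusted p = 0.606 with an estimated correlation; fry 0.0351). Fatty acid synthesis genes had a lower effect with furan in 3 of 13, 6 adjusted over the list alone (camera adjusted p = 0.00426; adjusted p = 0.667 with an estimated correlation). Camera also called ATF4 genes, with 1 of 19 members higher (0.0204; adjusted p = 0.667 with an estimated correlation), and acute phase genes, with 1 higher and 3 lower of 14 (0.0428; adjusted p = 0.667 with an estimated correlation). In all 936 of 12941 genes differed, 455 higher and 481 lower, by edgeR; limma voom gave 2002, and 519 differed at least 1.5-fold. Of 60 splits of the rats, 3 gave as many calls, so chance could not be excluded for this count.

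**Figure D3:**
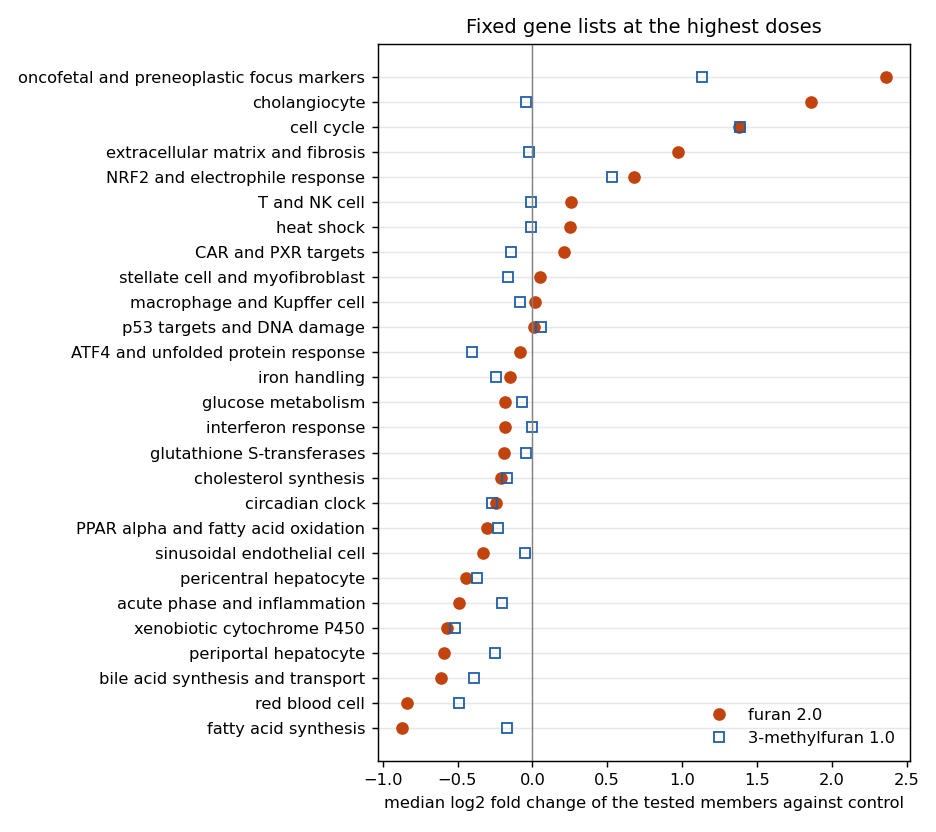
Median log2 fold change of the tested members of 27 gene lists at furan 2.0 (filled circles) and 3-methylfuran 1.0 (open squares). Cell cycle genes sat at 1.38 and 1.39, and matrix genes at 0.97 and -0.02.

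Genes that either compound moved overlapped beyond independence. Of 11885 genes tested in both experiments, 5617 were called at furan 2.0 and 5190 at 3-methylfuran 1.0. In the same direction 3432 were called, 1620 higher and 1812 lower, where independent lists would share 1226.8. In opposite directions 94 were called, where 1226.1 would be expected, and the difference between compounds was called for all 94. Fgf21, a hepatokine gene, rose by 1.36 ± 0.4 with furan and fell by 1.21 ± 0.31 with 3-methylfuran. Between furan 0.03 and 3-methylfuran 0.02 the Fgf21 interval was already 0.29 to 2.35. That gap may come from the controls or the experiments, which was not tested. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.702 and Spearman's rho 0.656.

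**Figure D4:**
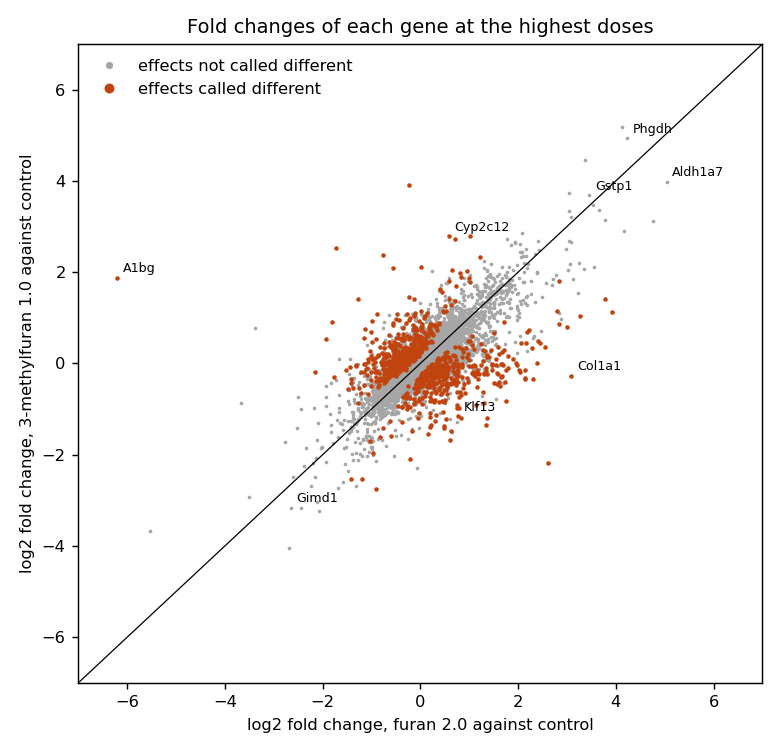
Log2 fold change of 11885 genes at furan 2.0 (horizontal) and 3-methylfuran 1.0 (vertical), with the 875 genes whose effects differed in colour and a diagonal of equal effects. Most genes lie in the quadrants of shared direction (75.4% had the same sign).

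At 3-methylfuran 1.0 the response was larger than at furan 0.5, the nearest dose below it. Phgdh differed by -3.51 ± 0.9, Gstp1 by -3.16 ± 0.63, the carbonic anhydrase gene Car2 by -2.32 ± 0.31 and Tyms by -0.99 ± 0.19, all lower with furan 0.5. Cell cycle genes had a lower effect in 10 of 30 members (16 adjusted over the list alone; camera adjusted p = 4.67e-07; adjusted p = 0.833 with an estimated correlation), and NRF2 genes in 11 of 23 (0.000272; adjusted p = 0.833 with an estimated correlation). Genes that 3-methylfuran 1.0 lowered stood higher: 8 of 23 P450 genes (11 adjusted over the list alone; camera adjusted p = 0.00175), 8 of 19 ATF4 genes (9 adjusted over the list alone; 0.00445) and 7 of 26 PPAR alpha targets (0.00494), each with adjusted p = 0.833 with an estimated correlation. P4ha2, a collagen hydroxylase gene, differed by 0.94 ± 0.1 and the pregnane X receptor gene Nr1i2 by 1.06 ± 0.13. EdgeR called 2774 genes, 1404 higher and 1370 lower, 1224 of them at least 1.5-fold. Cyp2e1 differed by -0.44 ± 0.22 (adjusted p = 0.133). Of 238 genes called at furan 0.5 and at 3-methylfuran 1.0, 178 moved the same way and 60 opposite ways (85.5 and 85.2 expected of independent lists).

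The 3 lower furan doses were each compared with the controls to see which genes move below 2.0. At 0.5, Zbtb16 rose from 6.57 ± 2.63 to 49.8 ± 26.4 CPM (n = 8 and 7; log2 fold change 2.92 ± 0.55), the nuclear receptor gene Nr1d1 of the clock by 2.22 ± 0.34, Prr32 by 2.27 ± 0.52 and Gpat3 by 2.21 ± 0.36. Aldh1a7 rose by 1.62 ± 0.41, Cd24 by 1.15 ± 0.23 and Spp1 by 3.42 ± 0.99, the last with 16.9 and 9.82 CPM in rats MD063_L and MD069_L and at most 0.836 CPM in the other 5. A1bg fell by 5.82 ± 1.39 and Cpa1 by 5.59. Gstp1 was not called (0.53 ± 0.29, adjusted p = 0.356), nor was Cyp2e1 (0.04 ± 0.16, adjusted p = 0.943). EdgeR called 402 genes, 191 higher and 211 lower, 249 with no filter on low counts and 157 at least 1.5-fold. Without rats MD063_L and MD069_L, a setting chosen after seeing the data, it called 326, 201 higher and 125 lower. Camera called cell cycle genes higher (0 of 30 members called, adjusted p = 0.0263) and cholesterol genes lower (2 of 24 called, 0.0263), each with adjusted p = 0.851 with an estimated correlation. Mki67 was 13.7 and 12 CPM in rats MD063_L and MD069_L and 2.89 to 6.52 CPM in the other 5, beside 1.75 to 7.97 CPM in controls. Clock genes rose in 2 and fell in 5 of 17, 4 and 8 adjusted over the list alone (fry for either direction, adjusted p = 0.000274; for 1 direction, fry 0.165 and camera 0.0783; adjusted p = 0.851 with an estimated correlation).

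At furan 0.12, Zbtb16 rose by 2.79 ± 0.54. Fkbp5, a steroid receptor co-chaperone gene, rose from 13.1 ± 1.55 to 57.5 ± 36.8 CPM (2.13 ± 0.36, n = 8 and 8). The zinc finger gene Zfp354a rose by 2.25 ± 0.38, Spsb4 by 1.89 ± 0.4 and Rhbdd2 by 1.54 ± 0.26. Each lay above the control mean in 8 of 8 rats, which the naming rule required of genes named by size. The cell cycle inhibitor gene Cdkn1a rose by 0.68 ± 0.18. Cyp26a1, which clears retinoic acid, fell by 1.36 ± 0.35, S1pr2 by 1.05 ± 0.24 and Vgll4 by 1.03 ± 0.23. EdgeR called 247 genes, 130 higher and 117 lower; limma voom called 279 higher and 304 lower, no filter gave 151, and 111 changed at least 1.5-fold. Camera called 0 of 31 lists (7 at an unadjusted p under 0.05; fry 0), and clock genes rose in 3 and fell in 2 of 17, 4 and 8 adjusted over the list alone (fry for either direction, adjusted p = 0.00571; for 1 direction, fry 0.51 and camera 0.21; adjusted p = 0.981 with an estimated correlation). At furan 0.03, 9 genes were called, 6 higher and 3 lower. Klf13 rose by 0.92 ± 0.17, the unfolded protein sensor gene Eif2ak3 by 0.41 ± 0.08, and the interleukin receptor gene Il4r fell by 0.42 ± 0.08 and Kcnk5 by 1.11 ± 0.23, with adjusted p of 0.0466 to 0.05 in edgeR. That count moved with the tool: DESeq2 gave 49, voom 95, no filter 1, run 1 alone 2, and the dose fitted with its controls alone 0 (1225 at an unadjusted p under 0.05). Camera called 5 lists at 0.03 without a called member: ATF4 (0.00223), matrix (0.0486) and macrophage genes (0.0134) higher, and glutathione S-transferases (0.0104) and PPAR alpha targets (0.00223) lower; with an estimated correlation adjusted p was 0.957 to 0.978. Cyp2e1 differed from control by 0.14 ± 0.16 at 0.12 and -0.09 ± 0.16 at 0.03 (adjusted p = 0.764 and 0.903).

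The lower 3-methylfuran doses were compared with their controls for the same purpose. At 0.075, Zbtb16 fell by 2.24 ± 0.5, again against controls of which 3 lay far below the others and nearer most dosed rats. The ubiquitin protease gene Usp2 fell by 1.88 ± 0.19, Lpin1, a phosphatidate phosphatase gene, by 1.35 ± 0.21 and Insig1, a brake on sterol synthesis, by 1.36 ± 0.29. Each of these genes lay below the control mean in 8 of 8 rats, which the naming rule required of genes named by size. Nr1d1 rose by 1.48 ± 0.34, Magi3 by 0.8 ± 0.09 and Lgr5, the R-spondin receptor gene of pericentral hepatocytes, by 1.55 ± 0.32. EdgeR called 163 genes, 52 higher and 111 lower, and 53 changed at least 1.5-fold; DESeq2 gave 283, the dose with its controls alone 95, no filter 106, 44 without the 4 rats above 25 M counts and 128 with all rats thinned to equal depth. Clock genes rose in 2 and fell in 3 of 17, 3 and 8 adjusted over the list alone (camera adjusted p = 0.00568; adjusted p = 0.164 with an estimated correlation; fry 0.00113). Camera also called PPAR alpha targets lower (0.00568), interferon genes higher (0.0124) and red blood cell markers lower (0.045), with 0 members called in each and adjusted p = 0.68, 0.68 and 0.606 with an estimated correlation. At 0.02, 4 genes were called: Arhgap24 (0.56 ± 0.1) and the synaptic scaffold gene Homer1 (0.54 ± 0.1) rose, and Ppan (-0.59 ± 0.11) and the heparan sulfate sulfotransferase gene Hs6st1 (-0.5 ± 0.1) fell. DESeq2 gave 18 there, voom 2 and run 1 alone 0 (674 at an unadjusted p under 0.05). Camera called NRF2 genes lower (0.0139) and interferon genes higher (0.000235) at 0.02, with adjusted p = 0.746 and 0.599 with an estimated correlation. Control rats MC508L and MC511L stood apart in NRF2-type genes, with Gsta3 at 119 and 61.3 CPM beside 2.11 to 9.2 CPM in the other controls and 2.2 to 7.51 CPM at 0.02. Cyp2e1 differed from control by 0.04 ± 0.13 at 0.075 and 0.07 ± 0.13 at 0.02 (adjusted p = 0.938 and 0.943).

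Lower doses of the compounds, which also do not match, were compared to see whether they differ below the range of the large responses. Between furan 0.12 and 3-methylfuran 0.075, Usp2 differed by 2.86 ± 0.32, Klf13 by 2.33 ± 0.28, the interleukin 6 receptor gene Il6r by 1.84 ± 0.22 and Nr1i2 by 0.96 ± 0.13, higher with furan, and Magi3 by -0.86 ± 0.16 and Arhgap24 by -0.75 ± 0.14. EdgeR called 328 genes, 210 higher and 118 lower, 205 at least 1.5-fold, and camera called 0 lists (3 at an unadjusted p under 0.05; fry 0). Of 22 genes called at both doses 20 moved in opposite directions (1.7 expected), and 2 the same way (1.6 expected). Gstp1 differed by 0.08 ± 0.63 (interval -1.17 to 1.34) and Cyp2e1 by 0.11 ± 0.21. Between furan 0.03 and 3-methylfuran 0.02, 64 genes differed, 45 higher and 19 lower, such as Lpin1 (2.3 ± 0.39), Klf13 (1.5 ± 0.28), Arhgap24 (-0.85 ± 0.14) and Homer1 (-0.73 ± 0.13). Voom gave 114 there, DESeq2 67 higher and 34 lower, and no filter 37. Camera called ATF4 genes higher with 0 of 19 members called (adjusted p = 0.00171; adjusted p = 0.836 with an estimated correlation; fry 0.371), and Cyp2e1 differed by -0.16 ± 0.21.

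Dose trends asked which genes rose or fell with dose as a linear term. The highest dose weighs most in such a slope, and proportion to dose was not tested. Per mg/kg body weight per day, Aldh1a7 rose by 2.42 ± 0.11, Gstp1 by 1.76 ± 0.1 and Cd24 by 1.33 ± 0.08 with furan, and the kallikrein inhibitor gene Serpina4 fell by 0.62 ± 0.04 and the apolipoprotein gene Apom by 0.63 ± 0.04. With 3-methylfuran the keratin gene Krt8 rose by 1.3 ± 0.06, Ica1 by 3.11 ± 0.15 and Cyp2c12, a female-predominant P450 gene, by 2.69 ± 0.12, and Cyp2d1 fell by 1.02 ± 0.06 and Serpina4 by 1.21 ± 0.07. Cyp2e1 changed by 0.45 ± 0.11 with 3-methylfuran (adjusted p = 0.00054) and by -0.04 ± 0.07 with furan, where it was not called (adjusted p = 0.618). EdgeR called 6620 genes with furan and 5724 with 3-methylfuran; without the highest dose the counts were 161 and 76.

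Neighbouring doses share their control rats, which alone makes their fold changes correlate. Of the genes called at furan 0.12 and 0.5, 175 were shared in the same direction, Zbtb16, Fkbp5 and Nr1d1 among them, where independent lists would share 3.9. In 20 simulations with shared controls and no effect 0 were shared for each pair of doses, which says little, as such data hold no effect to call. With the controls split between the doses, 16.4 were shared on average over 20 halvings, where 0.2 would be expected. The covariance of the fold changes was 0.0655, beside 0.0149 in the simulations. For furan 0.5 and 2.0, 320 were shared (93.4 of independent lists; 83 with split controls, 23.4 expected), with a covariance of 0.135 beside 0.015. For furan 0.03 and 0.12, 7 were shared (0.1 of independent lists; 0 with split controls, 0 expected), with a covariance of 0.0368 beside 0.0149. For 3-methylfuran 0.075 and 1.0, 149 were shared, Zbtb16, Usp2 and Lpin1 among them, and 1 moved opposite ways (36 of independent lists; 54.1 with split controls, 13.6 expected), with a covariance of 0.0545 beside 0.0118. For 3-methylfuran 0.02 and 0.075, 4 were shared (0 of independent lists; 0.5 with split controls, 0 expected), with a covariance of 0.0217 beside 0.0119.

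In the deposited comparison tables, 46, 369, 561 and 6356 genes had an adjusted p under 0.05 at furan 0.03, 0.12, 0.5 and 2.0, and 18, 268 and 5522 at 3-methylfuran 0.02, 0.075 and 1.0. Of the genes called here, 9 of 9, 245 of 247, 402 of 402 and 5762 of 5923 were also called there for furan, and 4 of 4, 162 of 163 and 5053 of 5207 for 3-methylfuran, each in the same direction. These tables come from the same libraries and are not independent evidence.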

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

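Chosen only after the results were seen were the endothelial marker test, the scores of rats ME086_L, ME089_L and ME092_L, the reading of the first principal component and the correlation of fold changes between compounds. The genes tested for a rat standing apart were also chosen after their values were seen. Of 122 groups tested for 1 rat standing apart from the others, 11 had one. Chance sets apart about 5 percent of groups, but with genes chosen by their values the 2 shares cannot be compared.

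Matrix and cholangiocyte genes at furan 2.0 were high in some rats and near control in others, with Col1a1 at 186, 184, 86.1 and 108 CPM in rats ME081_L, ME082_L, ME083_L and ME085_L and 12.1, 9.01 and 13.7 CPM in rats ME086_L, ME089_L and ME092_L. A tissue piece with more of every cell type other than hepatocytes would raise endothelial markers too, and their median log2 fold change was -0.33. The sign of that median rests on the scaling, since TMM factors were 1.021 to 1.405 at furan 2.0 and 0.894 to 0.963 in controls. A larger factor lowers every value of a rat, so the sign cannot decide this question. The order of the lists, with matrix and cholangiocyte genes above endothelial markers, does not depend on the scaling. An exchange of labels with furan 0.5 was examined by a score on the genes of the 3-methylfuran 1.0 response, in which Col1a1 was not called. Rats ME089_L and ME092_L scored 0.372 and 0.418, beside at most 0.192 at furan 0.5 (SD 0.07), which argues against it. Rat ME086_L scored 0.197 and had no partner by score: 0 rats scored within the other group's range, and the highest at furan 0.5, 0.192, lay below the other 6 furan 2.0 rats (at least 0.372) by more than the SD. The first principal component, the axis of largest variation among the furan rats, did not separate the groups. Rats MD063_L and MD069_L of furan 0.5 lay at 24.8 and 17.4 there, above rats ME086_L (6.2) and ME089_L (16.9). An exchange therefore stays open for rats ME086_L and ME089_L. A single wrong label, which needs no partner, was not tested. A change in bile duct cells and matrix-forming cells themselves may underlie the pattern, and stays open as a hypothesis.

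In the 3-methylfuran controls, Gstp1 was 21.6 and 18.7 CPM in rats MC508L and MC511L and 6.75 to 8.05 CPM in the others, and Akr7a3 was 188 and 322 CPM beside 23.9 to 84.3. An exchange of labels with 3-methylfuran 1.0 is argued against: 0 rats of that dose scored within the range of the controls. The high values were in these 2 rats and also in rats MB549L and MB551L of 3-methylfuran 0.075 (Gstp1 23.8 and 21.5 CPM). What raised them stays open, and no biological explanation was tested.

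Genes called at furan 0.12 tended to move the other way at 3-methylfuran 0.075 (correlation of the fold changes -0.42, which describes the pattern and tests no explanation of it). For a change that grows with the dose of furan, the prediction written beforehand was that most of them would move further in the same direction at furan 2.0. It was not met, as 38.9 percent did, but folds of genes picked at 0.12 are too large there, so this share cannot decide. At 2.0, 160 were called in the same direction and 1 in the opposite. Both doses were tested against the same control rats, which alone favours the same direction, so these counts cannot decide either and the explanation stays open. Differences between rats in hormone, feeding or clock state when the liver was taken are a candidate explanation. Over the 8 control rats of 3-methylfuran, untreated, the same genes had a mean signed correlation of 0.08, above that of all 10000 random sets. These genes thus varied together in untreated rats. Genes regulated together for any reason, targets of a compound included, would exceed random sets, so this does not favour the candidate explanation. Kit and experiment go with the compound, so a difference between the experiments stays open.

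Total counts stood apart in rat MA528L of 3-methylfuran 0.02 (17.6 M) and rat MB048_L of furan 0.12 (20.5 M). A1bg was 142 CPM and Spp1 2.88 CPM in rat MA030_L of furan 0.03, each far above the other 7 rats. Col1a1 was 91 CPM in rat MD063_L and Phgdh 12.4 CPM in rat MD069_L of furan 0.5. Cyp2e1 was 4.99e+03 CPM in rat ME086_L of furan 2.0, the rat with the lowest Gstp1 of that group. Fkbp5 was 34.9 CPM in rat MA531L and Gpx2 1.21 CPM in rat MA532L of 3-methylfuran 0.02. Gstp1 was 638 CPM in rat ME587L of 3-methylfuran 1.0, and Zbtb16 11.2 CPM in rat MB542L of 3-methylfuran 0.075.

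Effects differed between the compounds, by a test of each difference, for 936 genes between furan 2.0 and 3-methylfuran 1.0, 2774 between furan 0.5 and 3-methylfuran 1.0, 328 between furan 0.12 and 3-methylfuran 0.075 and 64 between furan 0.03 and 3-methylfuran 0.02. For the 936, 3 of 60 splits gave as many, the highest of the others 3937, so chance could not be excluded. Such a split points to a structure of the samples; splits exchange dosed rats with controls, so uneven ones carry dose effects, and no test separated these from other structure. For the other 3 counts the highest of the other splits were 377, 35 and 3, each with 1 of 60 as large. This argues against chance, but 60 splits cannot exclude it. Between furan 2.0 and 3-methylfuran 1.0, 94 genes were called in opposite directions with the difference also called.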

How the results depend on the processing

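Chosen only after the data were seen were the settings without controls MC508L and MC511L, without 2 rats of furan 0.5, without the 4 deepest rats and with counts thinned. No paired analysis was possible because the labels give no replicate number that pairs rats across groups. An order by rat number, seen afterwards, was not modelled. At furan 0.03 the second principal component was 13.2, 19.5 and 13.9 in rats MA021_L, MA022_L and MA023_L. It was -14.2, -15.7 and -21 in rats MA027_L, MA029_L and MA030_L. At furan 0.5 it showed no such order, with 8.7 in rat MD062_L and 8.5 in rat MD071_L. What underlies the order was not tested. Of 162 alternative counts, 108 stayed within 1.5 times the reported count and 54 did not. The cause of the others was not tested unless given here.

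With a fold of at least 1.5 required, which can only lower a count, furan 0.03, 0.12, 0.5 and 2.0 gave 5, 111, 157 and 2229 genes, 3-methylfuran 0.02, 0.075 and 1.0 gave 1, 53 and 1587, and the differences gave 519 (2.0 and 1.0), 1224 (0.5 and 1.0) and 205 (0.12 and 0.075). DESeq2 gave 49 at furan 0.03, 18 and 283 at 3-methylfuran 0.02 and 0.075, and 1.0e+02 for the lowest doses' difference. Limma voom gave 95 and 5.8e+02 at furan 0.03 and 0.12, 2 at 3-methylfuran 0.02, and 2002 and 114 for the differences of the highest and lowest doses. With no filter on low counts, furan 0.03, 0.12 and 0.5 gave 1, 151 and 249, 3-methylfuran 0.075 gave 106 and the lowest doses' difference 37.

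Run 1 alone, with fewer reads, gave 2 genes at furan 0.03 and 0 at 3-methylfuran 0.02 by edgeR (674 at an unadjusted p under 0.05). With the dose and its controls alone, and so fewer rats, edgeR gave 0 at furan 0.03 (1225 unadjusted), 0 at 3-methylfuran 0.02 (766) and 95 at 0.075. Without controls MC508L and MC511L, 3-methylfuran 0.02 gave 0 (692 unadjusted), and without the 4 rats above 25 M counts, with fewer rats, 0.075 gave 44, beside 128 with all rats thinned to equal depth (163 reported). Without rats MD063_L and MD069_L furan 0.5 gave 326, 201 higher and 125 lower. Without the highest dose the trends gave 161 genes for furan and 76 for 3-methylfuran.

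With the controls split between doses, shared calls were 0, 16.4 and 83 for neighbouring furan doses and 0.5 and 54.1 for 3-methylfuran, with fewer controls per test. With an estimated correlation, camera called 0 lists in every comparison, where it had called 5, 2 and 15 at furan 0.03, 0.5 and 2.0, 2, 4 and 6 at 3-methylfuran 0.02, 0.075 and 1.0, and 6, 5 and 1 for the differences. Fry called 0 at furan 0.03 and 0.5, 0, 1 and 18 at the 3-methylfuran doses, and 2 and 0 for the differences of the highest and lowest doses.

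Leaving out each rat in turn gave 5353 to 6355 genes at furan 2.0 and 4880 to 5196 at 3-methylfuran 1.0. For the named genes, 2616 alternative values gave 2436 on the same side of the threshold, 179 past it no longer, 1 newly past it (the Cyp2e1 difference by voom) and 0 reversed. Apart from Cyp2e1 only called values entered, so no other value could newly pass. With run 1 alone, and so fewer reads, 25 of 282 named values no longer passed the threshold. Values picked for passing can be lost without an effect of depth. Over all genes run 1 alone called 4963 at furan 2.0 and 3825 at 3-methylfuran 1.0, beside 5923 and 5207 with all runs.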

Other observations

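No test in this part was chosen after its result was seen, but the genes of the next paragraph were named, and the chromosomes compared, after the data were seen.

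Cyp2c12, a female-predominant P450 gene, rose from 13.6 ± 2.81 to 93.7 ± 24.8 CPM at 3-methylfuran 1.0 (SD, n = 8 and 8; log2 fold change 2.78 ± 0.17 SE), and was not called at furan 2.0 (0.59 ± 0.45, edgeR adjusted p = 0.291); the difference was -2.21 ± 0.51. That difference rests on the furan controls, of which 5 had 42.6 to 89.1 CPM and 3 had 11.3 to 16.7 CPM, beside 35.1 to 85.3 CPM at furan 2.0 and 58.3 to 135 CPM at 3-methylfuran 1.0. A1bg fell by 6.21 ± 1.38 at furan 2.0, against the same 5 controls at 14.3 to 60.6 CPM and the same 3 at 0.405 to 1.41 CPM. It rose by 1.88 ± 0.53 at 3-methylfuran 1.0, but near the floor. There it was 0.203 to 1.58 CPM beside 0 to 0.67 CPM in the 3-methylfuran controls, and these ranges overlap.

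Other splits of the same rats never called as many genes as the real ones at any dose, each with 1 of 100 splits as large. This argues against chance, but 100 splits for each of several counts cannot exclude it. The counts of 9 at furan 0.03 and 4 at 3-methylfuran 0.02 also fell to 0 with the dose and its controls alone. The real count and the highest other were 9 and 1, 247 and 157, 402 and 35 and 5923 and 3386 at the furan doses, and 4 and 2, 163 and 57 and 5207 and 3548 at the 3-methylfuran doses. For the trends they were 6620 and 84 for furan and 5724 and 1169 for 3-methylfuran. For the genes shared between furan 2.0 and 3-methylfuran 1.0 the splits say nothing, since 88 and 91 of the others called no gene and the highest other pair shared 0.

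For the numbers of lists called by camera, chance could not be excluded. At furan 0.03, 0.12, 0.5 and 2.0, 56, 100, 96 and 8 of 100 splits called as many lists, the real values 5, 0, 2 and 15 and the highest others 12, 15, 14 and 17. At 3-methylfuran 0.02, 0.075 and 1.0, 94, 77 and 52 did, with real values 2, 4 and 6 and highest others 11, 14 and 12. For the differences, from the highest doses down, 43, 40, 60 and 57 of 60 did, with real values 6, 5, 0 and 1 and highest others 15, 11, 15 and 10.

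Of the named protein-coding genes that the reference places on chromosome 19, 0.6% share a symbol with the deposited tables, beside 56.9 to 81% on other chromosomes. List members there, such as Hmox1, Nqo1 and Hp, were not analysed here.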
